A study of Mus musculus with 11 samples.

How the data were processed

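A barcoded pool of mouse pancreatic ductal adenocarcinoma (PDAC) cell lines had been injected into the vein of 129/Bl6 F1 mice that had first received vehicle or 6-hydroxydopamine (6-OHDA), a toxin taken up by sympathetic nerve endings, per the labels. Lungs were analysed 3 weeks later. There were 6 vehicle samples and 5 6-OHDA samples, and groups and sample numbers were taken from the sample titles. The labels do not state that each library came from a separate mouse, so the p-values measure the spread between these samples, which may in part be technical.

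Per the labels' protocols, a benchmark spike-in cell line was added to each weighed tissue before DNA extraction, and a cassette named as U6, CLID, rBC and sgRNA was amplified from 32 µg of genomic DNA in 27 PCR cycles. The deposited values are read counts per barcode cluster, with 1 table per sample, per the file headers. The tool that grouped reads into barcode clusters, and its settings, are not given in the sources used here. Each deposited row pairs a 20-base barcode with its count. All 135364 listings in the 11 tables began with 4 bases followed by 12 random bases interrupted by 4 fixed G bases. The 4 leading bases were read as the identifier of a line of the pool, which is an inference from the layout of the cassette. No name of a cell line, sgRNA or spike-in accompanied the rows. Listings with an undetermined base, 4 in all, were dropped.

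The planned scale was the spike-in. Since no row could be recognised as the spike-in by name, total lung tumour burden, burden per line and every size in cell numbers were left out, and sgRNA groups were not compared. The fallback fixed for that case was used. Every library was thinned at random without replacement to the smallest read total, 6436469, and a barcode with at least 10 thinned reads was counted as a colony. Colony sizes are in RPM, reads per 1000000 barcode reads of the library, and the minimum equals 1.55 RPM. On this scale the sizes of a library add up to nearly the same total, so its mean colony size is close to the inverse of its colony number, and the 2 results are not independent. A library from a lung with more tumour cells has fewer reads per cell, which can hide its small colonies. Repeating the thinning 20 times moved the log2 colony number of a sample by an SD of at most 0.0042. PCR reads carry no molecular identifiers here, so read numbers are not numbers of cells or molecules.

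Library depth ranged from 6436469 to 15665492 reads, with 118983303 reads in all. Barcodes with a single read made up 20.8 to 49.2% of the barcodes of a library and at most 0.055% of its reads. The highest correlation of read counts over barcodes between any 2 libraries was 0.108, so no library was treated as a duplicate of another.

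Values with 1 number per sample were compared by exact two-sided permutation of the group labels over all 462 splits of the samples, on log2 values except for percentages and the Gini coefficient. The smallest p these splits allow is 0.0043. The 5 statistics of colony size were adjusted together by the Benjamini-Hochberg method. Colony number per identifier was tested with edgeR 4.0.16 (quasi-likelihood test, equal library sizes) for identifiers with at least 5 colonies in 1 or more samples. Reads per identifier were tested with the same edgeR test after TMM scaling, leaving out identifiers under 10 reads in most of the samples of both groups. Mean colony size per identifier was tested with limma 3.58.1 where at least 3 samples per group held 5 or more colonies. The standard errors given for edgeR are the log2 change divided by the square root of its F statistic. Adjusted p-values are Benjamini-Hochberg values over the identifiers of a test, with a threshold of 0.05. The spread of responses over identifiers was tested by permuting the sample labels over all splits, on log2(value + 1), for colony number as planned and for share of reads in place of the planned burden per line. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

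The tests were checked on simulated data built from the means and spread of the real identifiers, with 10 identifiers changed in each of 20 simulations. For colony number over 38 identifiers, edgeR called 56.5% of those changed 4-fold and 96.0% of those changed 16-fold. For reads over 37 identifiers the shares were 50.5% and 82.0%, and for limma on colony size over 30 identifiers 91.5% and 100%. At most 2.75% of unchanged identifiers were called. The simulated identifiers varied independently and changed in both directions, whereas the real colony numbers mostly moved together. Smaller changes were not simulated, so the power to find them is not known.

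The rule for naming identifiers took the 10 with the highest mean share of reads in vehicle, up to 10 with the largest change in colony number past the threshold, and the 3 with the smallest change among those with at least 20 colonies in every sample. It also described the largest barcode of each sample by its identifier. The tests, apart from that replacement, this rule and most alternatives were chosen before the data were examined. The rule gave 11 identifiers. GATC and CAGA fall outside it and were named after their values were seen. Alternatives were other colony minima, sizes without thinning, merging of barcodes 1 base apart, removal of shared barcodes or of the largest barcode, DESeq2 1.42.0 in place of edgeR, permutation tests per identifier, the sample number as a block, and leaving out each sample in turn. The alternative with no minimum also used no thinning. Same-numbered samples of the groups were not described as sharing a mouse or a day.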

Results

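Barcode abundance was measured by sequencing in 11 lung samples collected 3 weeks after intravenous injection of a barcoded pool of pancreatic ductal adenocarcinoma cell lines. Of these, 6 came from vehicle-treated mice and 5 from mice given 6-hydroxydopamine (6-OHDA), which destroys sympathetic nerve endings. The libraries held 6436469 to 15665492 reads and 4776 to 20865 barcodes. Depth differed little between the groups, with a log2 difference of 0.14 (exact permutation p = 0.606). A barcode was taken to stand for the descendants of a tagged cell, and its read count for the relative size of that colony. If tagged cells had divided before injection, several cells with the same barcode could have seeded a lung. Colony numbers are therefore numbers of distinct barcodes, not of seeding events. Of the colonies, 49.2% carried a barcode seen in 2 or more samples. The 4 leading bases of a barcode were taken to identify a line of the pool, whose name was not used here.

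The first comparison asked whether loss of sympathetic nerves changed how many colonies the lung held. Libraries from 6-OHDA-treated mice held 8365 ± 2536 colonies (SD, n = 5) and those from vehicle-treated mice 4431 ± 2930 (SD, n = 6), after all were thinned to the same read total. This is a 2.17-fold higher geometric mean, a log2 difference of 1.12 with an SE of 0.43. All 5 samples of the 6-OHDA group lay above the vehicle mean, and 2 lay above every vehicle sample. The vehicle samples were widely spread. Samples 1, 2, 5 and 6 held 2013, 3385, 1965 and 2930 colonies, all below the lowest 6-OHDA sample at 5548, whereas samples 3 and 4 held 7999 and 8292, within the 6-OHDA range. Before thinning, vehicle samples 3 and 4 were also the deepest vehicle libraries. They had 15665492 and 13410390 reads, against 6436469 to 9970985 in the other vehicle samples. The difference in colony number did not pass the threshold (exact permutation p = 0.0519). It passed without vehicle sample 3 (exact permutation p = 0.0317) and without vehicle sample 4 (exact permutation p = 0.0238). A minimum of 2 reads (exact permutation p = 0.0390) and merging of barcodes 1 base apart (exact permutation p = 0.0476) also let it pass. So did counting with neither a minimum nor thinning, where depth was not equal (exact permutation p = 0.0433).

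Colony size was compared next, as each colony's part of the library. The median colony size was 18.5 ± 3.85 RPM (reads per 1000000 reads of the library; SD, n = 5) against 45.0 ± 21.9 RPM in vehicle (SD, n = 6), a log2 difference of -1.14 with an SE of 0.35. All 5 samples of the 6-OHDA group lay below the vehicle mean, and 4 of the 6 vehicle samples lay above every 6-OHDA sample. The exact permutation p was 0.0260 before and 0.0563 after adjustment over the 5 size statistics. At the upper end, the 99th percentile was 1635 ± 555 RPM in the 6-OHDA group and 3874 ± 2130 in vehicle (log2 difference -1.08, adjusted exact permutation p = 0.0563). Mean size, on a scale with a fixed total, mirrored the colony number, at 129 ± 39.6 against 314 ± 171 RPM. With neither a minimum on reads nor thinning the difference in median size turned to 1.09. The median passed the threshold when reads were scaled by identifier GATC (log2 difference -0.84, adjusted exact permutation p = 0.0433), whereas the other 4 statistics on that scale, from -0.73 to -0.59, did not. All 5 statistics passed without vehicle sample 3 or vehicle sample 4 (adjusted exact permutation p = 0.0317 in each case).

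Small colonies, those with fewer than 40 thinned reads, made up 28.4 ± 2.87% of colonies in the 6-OHDA group (n = 5) and 21.3 ± 3.90% in vehicle (n = 6). The difference of 7.13 percentage points, with an SE of 2.05, passed the threshold (exact permutation p = 0.0173). Vehicle samples ranged from 16.7 to 26.7%, and 5 of the 6 lay below every 6-OHDA sample. At a fixed read total more colonies leave fewer reads for each, so this part is not independent of the colony number. Over all 9 comparisons of this kind its adjusted p was 0.0724 by the same exact permutation test. With a minimum of 2 reads the difference turned to -0.732 points, and with neither a minimum nor thinning to -9.79 points. Small colonies were redefined to match, and neither difference passed.

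**Figure D1:**
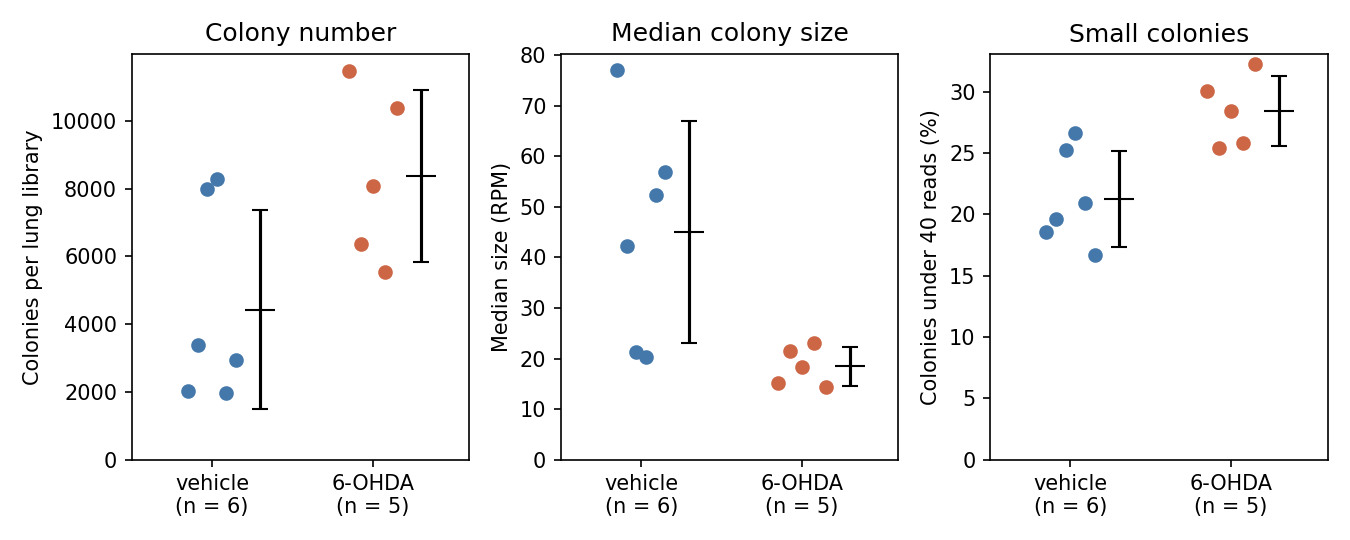
Number of colonies, median colony size in RPM and percentage of colonies under 40 thinned reads in each lung library, with vehicle samples (n = 6) in blue and 6-OHDA samples (n = 5) in orange. Points are samples, and black bars give the mean and SD; 2 vehicle samples, at 7999 and 8292 colonies, lie among the 6-OHDA samples.

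Concentration of the reads in a few colonies did not differ detectably between the groups. The 10 largest barcodes held 12.3 ± 4.87% of reads in vehicle (n = 6) and 7.59 ± 2.07% in the 6-OHDA group (n = 5), a difference of -4.67 points that did not pass the threshold (exact permutation p = 0.0866) except without vehicle sample 4 (exact permutation p = 0.0159). The Gini coefficient of colony sizes, a measure of inequality, was 0.807 in both groups, with SDs of 0.0171 in vehicle and 0.0130 in the 6-OHDA group (exact permutation p = 0.965). The largest barcode of a library held 0.552 to 4.07% of its reads. It carried identifier AACC in 7 samples and GTTG in 6-OHDA samples 1 and 3. In vehicle sample 2 it carried ATCG and made up 98.0% of the reads of that identifier, and in vehicle sample 5 it carried ACCT and made up 50.5% of that identifier's reads.

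The lines were unevenly represented in the lungs. Identifiers AACC, GTTG and CCTT together made up 79.1% of all reads, and the 11 named identifiers 94.3%. AACC was the most abundant in every sample, with 58.6 ± 10.1% of reads in vehicle and 45.0 ± 5.51% in the 6-OHDA group. GTTG held 13.5 ± 11.9% in vehicle and 31.4 ± 4.99% in the 6-OHDA group, and 5 of the 6 vehicle samples lay below every 6-OHDA sample. Vehicle sample 4, at 35.3%, was the exception. CCTT held 6.01 ± 1.63% in vehicle and 4.05 ± 0.885% in the 6-OHDA group, and AGGT 4.53 ± 1.76% and 3.28 ± 0.549%.

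**Figure D2:**
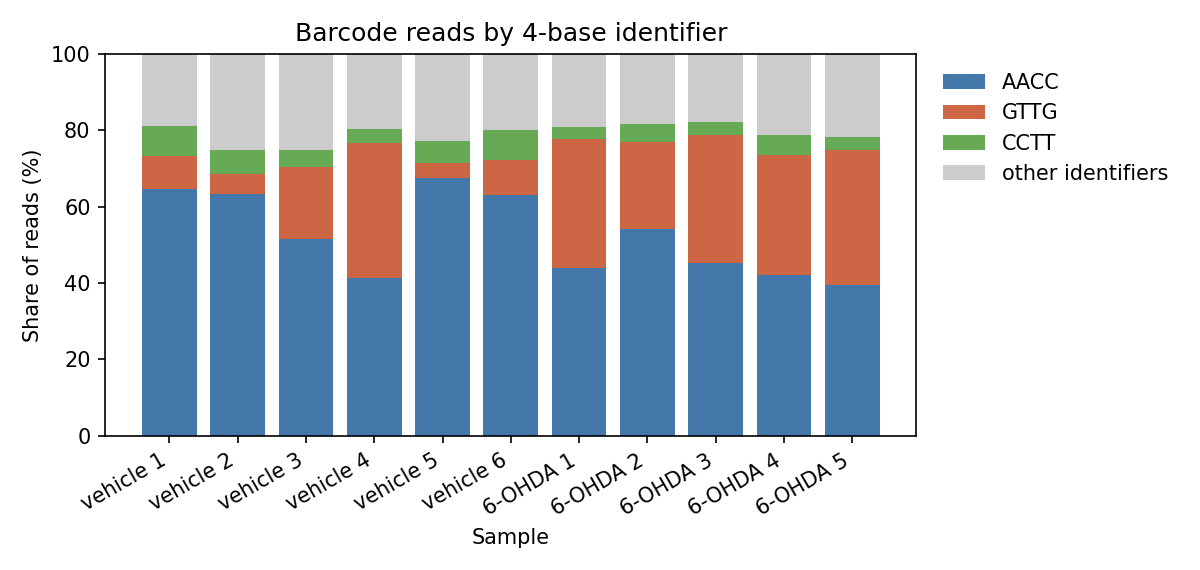
Share of barcode reads (%) by 4-base identifier in each lung library, stacked for AACC, GTTG, CCTT and all other identifiers. GTTG spans 3.93 to 35.3% in the vehicle samples and 22.8 to 35.4% in the 6-OHDA samples.

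Whether lines differed in their response was asked first from the number of colonies per identifier. Of 38 identifiers tested, 36 had more colonies in the 6-OHDA group and 2 had fewer. As many were higher in 95 of the 462 splits of the samples, and relative to all colonies of a sample (TMM scaling) 21 were higher and 17 lower. None passed an adjusted p of 0.05 in edgeR's quasi-likelihood test. At an unadjusted p under 0.05, 5 were higher and 1 lower, and exact permutation tests per identifier gave 11 at an unadjusted p under 0.05 and 0 after adjustment. All 11 named identifiers had more colonies in the 6-OHDA group, with log2 changes from 0.58 to 1.36, but relative to all colonies of a sample 8 of them had values below 0, down to -0.83. GTTG had the highest, with 1213 ± 410 colonies against 471 ± 483 (log2 change 1.36, SE 0.53, edgeR adjusted p = 0.172). AACC had 1509 ± 494 against 901 ± 429 (log2 change 0.74, SE 0.43, edgeR adjusted p = 0.204). CTGT, AGGT and CCTT had the smallest changes among well-populated identifiers, at 0.58, 0.62 and 0.70. ACCT, with 119 ± 29.1 colonies against 53.7 ± 28.9, was above every vehicle sample in 4 of 5 6-OHDA samples. Without vehicle sample 4, edgeR called 8 identifiers, 7 of them higher, among them GTTG (log2 change 1.91, adjusted p = 0.0036). Without 6-OHDA sample 2 it called CAGA and GATC, and without vehicle sample 3 or vehicle sample 6 GATC alone.

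The identifiers with the lowest edgeR p-values lay outside the rule and were picked after their values were seen. GATC had 48.3 ± 47.8 colonies in vehicle and 6.40 ± 4.72 in the 6-OHDA group (log2 change -2.89, SE 0.87, edgeR adjusted p = 0.0654, unadjusted exact permutation p = 0.108). Its barcodes had a median of only 3 to 7 reads before thinning in every library, close to the minimum of 10. Counted without a minimum and without thinning, GATC barcodes numbered 474 ± 270 in vehicle and 400 ± 108 in the 6-OHDA group (log2 difference -0.08, exact permutation p = 0.840). CAGA had 0 colonies in all 6 vehicle samples and in 6-OHDA samples 1 and 2, and 3, 3 and 9 in 6-OHDA samples 3, 4 and 5 (edgeR adjusted p = 0.103, unadjusted exact permutation p = 0.121). By exact permutation the lowest p was that of ACCT, a named identifier, at 0.00866 before and 0.112 after adjustment.

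The second comparison of lines used each identifier's part of the reads, which does not depend on the total burden. Of 37 identifiers, 19 were higher and 18 lower in the 6-OHDA group after TMM scaling, and 0 passed an adjusted p of 0.05 in edgeR. An unadjusted p under 0.05 was reached by 5. DESeq2 called 1, CAGA, and exact permutation tests per identifier called 0, with 8 at an unadjusted p under 0.05. Without TMM scaling 24 were higher and 13 lower, the median log2 change moved from 0.06 to 0.17, and edgeR called CAGA. CAGA was also called without 6-OHDA sample 1 and without 6-OHDA sample 2. GTTG had a log2 change of 0.99 (SE 0.46, edgeR adjusted p = 0.281), and 9 of the 11 named identifiers had values below 0, such as CCTT at -1.08 (SE 0.47, edgeR adjusted p = 0.281) and AACC at -0.82 (SE 0.43, edgeR adjusted p = 0.285). These changes are relative to the TMM scale, and on the plain share of reads they were 1.21 for GTTG, -0.57 for CCTT and -0.38 for AACC.

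The spread over identifiers of the change in share of reads passed the threshold, whereas that of colony number did not. Share of reads was used here in place of the planned burden per line, which could not be computed. The variance over identifiers of the log2 difference was 1.76, larger than in nearly all other splits of the samples (permutation p = 0.0195). The 21 identifiers that lacked 20 colonies in some sample, with 2.53% of all reads, made up 75.3% of it, against a median of 85.9% in the 461 other splits, so this part is not specific to the real groups. Tested apart, the variance was 2.03 over these 21 (permutation p = 0.0368) and 0.423 over the other 16 (permutation p = 0.0411). Identifiers as rare as many of the 21 can be missed in samples with few colonies. For them the test cannot separate responses of single lines from a change shared by all. Without 6-OHDA sample 3, 4 or 5 the permutation p over all 37 was 0.0810, 0.0571 and 0.0619. For colony number the variance was 0.487 and did not pass (permutation p = 0.0606). It was 0.210 without GATC (permutation p = 0.0628) and 0.159 over the 16 well-populated identifiers (permutation p = 0.0563). It passed at minima 3 and 10 times higher (permutation p = 0.0368 and 0.0216), and without vehicle sample 3 or vehicle sample 4 (permutation p = 0.0397 and 0.0317).

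Mean colony size per identifier was lower in the 6-OHDA group for 28 of 30 identifiers, and none passed an adjusted p of 0.05 in limma. On the RPM scale this mean is close to the identifier's share of reads divided by its colony number. The lower sizes are therefore not independent of the higher colony numbers. How many splits of the samples gave as many lower was not counted. An unadjusted p under 0.05 was reached by 15, all lower. AGAG had a log2 change of -1.67 (SE 0.56, limma adjusted p = 0.0609), CCTT -1.32 (SE 0.47, limma adjusted p = 0.0609) and AACC -1.17 (SE 0.47, limma adjusted p = 0.0650), while GTTG had -0.38 (SE 0.38, limma adjusted p = 0.372). The median log2 change was -1.09. It was -0.65 when reads were scaled by identifier GATC, and -0.16 with neither a minimum nor thinning, where 67 of 101 identifiers were lower and 34 higher. Limma called 14 identifiers without vehicle sample 3, 16 without vehicle sample 4, of which 15 were lower and 1 higher, 11 without 6-OHDA sample 4, 3 at a minimum 3 times higher and 5 without thinning.

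Many barcodes recurred between samples. Of 47042 distinct barcodes counted as colonies, 12311 were found in 2 or more samples and 3 in all 11. If each sample had drawn its colonies at random from all these barcodes, 20714 would have been expected in 2 or more. That number takes the barcodes seen as the whole pool, and a larger pool would give fewer. The lower number found therefore cannot show whether recurrence was above or below chance. The part of recurring colonies depended on the identifier, at 82.3% of colonies for GTTG, 63.1% for AACC and 4.35% for GATC. The value for GATC rests on the 322 of its barcodes that passed the minimum. Without a minimum and without thinning, GATC had 4843 barcodes summed over the libraries, of which 3301 were distinct, so more of them recurred. Overlap relative to expectation was not detectably higher within than between the groups (log2 difference 0.050, exact permutation p = 0.143), although it passed at a minimum 3 times higher (log2 difference 0.068, exact permutation p = 0.0260).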

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

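All of the explanations in this part were tested only after the results had been seen; the outlier criterion was planned, and so was the test of the difference between identifiers, but on colony number and on burden, which could not be computed and was replaced by share of reads.

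Single samples stood far from the rest of their group in 6 of 64 groups of values examined, where the nominal rate gives about 3.2. The groups are not independent of one another, so this rate is only a rough guide. ATCG made up 4.15% of reads in vehicle sample 2, nearly all of it from a single barcode. This identifier was examined only because that barcode was the largest of its sample, so its high share there followed from the choice. ACCT reached 4.68% in vehicle sample 5, with 50.5% of that identifier's reads from a single barcode. Among the 6-OHDA samples, AGTC reached 5.47% in sample 5, AGGT 4.25% and CTTC 2.86% in sample 4, and ATCG had 89 colonies in sample 1.

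The change in share of reads with 6-OHDA was more spread over identifiers than in nearly all other splits (permutation p = 0.0195). GTTG, the second most abundant identifier, held a mean of 13.5% in vehicle and 31.4% in the 6-OHDA group, and AACC 58.6% and 45.0%, with unadjusted exact permutation p = 0.0216 and 0.0433, and 0.200 for both after adjustment over 37 identifiers. These abundant identifiers added 0.972% and 2.24% of the variance, while CAGA, TGAA, TCAG, TGAT, CACT and TGAG, with 0.165% of all reads together, added 60.9%. The 21 identifiers without 20 colonies in every sample took 75.3% of the variance, against a median of 85.9% in the other splits. Over the 16 identifiers with at least 20 colonies in every sample, a set added after seeing the data, the variance was 0.423 (permutation p = 0.0411). No explanation of this spread was tested, and the variance over all 37 identifiers passed in 8 of the 11 analyses that left out a sample.

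The higher colony number in the 6-OHDA libraries missed the threshold, and vehicle samples 3 and 4 resembled the 6-OHDA samples. These were also the deepest vehicle libraries, so within the vehicle group the highest colony numbers went with depth even after thinning. Depth differed between the groups by a log2 of only 0.14, so thinning could hardly have removed the difference. Thinning every library to the same depth kept 96.9% of the log2 difference. Together these values argue against the number of reads as the whole cause. They cannot address library properties that go with depth. Removing the 100 largest barcodes of every library kept 95.4%, which argues against a few barcodes taking most of the reads. A minimum of 100 thinned reads kept 74.7%, and 71.3% at the least with any sample left out, which argues against sequencing errors and stray reads as the whole cause. Other explanations were not tested. Among them, an effect of 6-OHDA on seeding and differences between mice in the dose of cells that reached the lung remain open, as does chance. A number of barcodes above a minimum at 3 weeks cannot separate seeding from later survival or growth.

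The tests over identifiers called 0 in the real grouping for colony number, for share of reads and for colony size. With 0 calls, all 100 of the 100 splits drawn for each necessarily gave at least as many, so the splits exclude nothing about chance. Of the other splits, 12 called any identifier for colony number, with 36 at most, 8 for share of reads, with 13 at most, and 5 for colony size, with 20 at most.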

How the results depend on the processing

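The difference in colony number kept its direction in all 24 alternatives. It passed the threshold at a minimum of 2 reads (1.09), with neither a minimum nor thinning (0.89) and with similar barcodes merged (1.12). With a sample left out it ranged from 0.94 to 1.35. Median size turned to 1.09 with neither a minimum nor thinning, where barcodes of a single read enter. It passed at -0.84 on the scale of GATC reads, an alternative added after seeing the data. With a sample left out, the size differences ranged from -1.34 to -0.96 (median), -1.35 to -0.94 (mean), -1.42 to -0.97 (90th percentile), -1.34 to -0.92 (95th) and -1.32 to -0.88 (99th). The share of small colonies turned to -0.732 points at 2 reads and -9.79 with neither a minimum nor thinning, and ranged from 6.16 to 8.21 with a sample left out. The share in the 10 largest barcodes ranged from -6.11 to -3.61 points. The Gini difference, near 0 throughout, was -0.00869 and -0.0312 at minima 3 and 10 times higher and -0.00288 at 2 reads. It was -0.0151 with neither a minimum nor thinning, and -0.00301 to 0.00554 with a sample left out. The cause of these shifts was not tested.

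No pairing by sample number was seen in the shares of 16 identifiers. The correlations of same-numbered deviations were -0.48, 0.019, 0.36, -0.17 and -0.34, and none matched its own number best. A pairing that leaves no mark on these shares is not excluded. With the number as a replicate block, 5 pairs allow no exact p under 0.0625, so the share of small colonies (6.21 points) could not pass, and the Gini difference was -0.00235. The block called 0 identifiers in all 3 tests.

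Counts of called identifiers moved from 0. Colony number gave 1 without shared barcodes, 1 at 2 reads, 2 without a filter and 0 to 8 with a sample left out. Size gave 3 at a minimum 3 times higher, 5 without thinning (added) and 0 to 16. Share of reads gave 1 with DESeq2, 1 without TMM (added) and 0 to 1. The variance over identifiers for colony number passed at minima 3 and 10 times higher (0.250 and 0.296) and ranged from 0.357 to 0.725, and for share of reads from 1.40 to 2.30. Overlap within groups passed at a minimum 3 times higher (0.068, added). Colony number relative to all colonies of a sample (TMM, added) turned AACC to -0.66, CCTT to -0.72, AGGT to -0.75, AGTC to -0.43, AGAG to -0.23, CTTC to -0.28, CTGT to -0.83 and ACCT to -0.16. In share of reads, CTTC turned to 0.028 without TMM, GGAA to -0.037 without vehicle sample 6 (0.33 without vehicle sample 2), and ATCG, at -2.89 without vehicle sample 6, turned to 0.49 without vehicle sample 2 and 0.65 without the largest barcodes. Alternatives that need a recognised spike-in were not run. Depth limits the smallest colonies: 10 thinned reads is the floor in every library.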

Other observations

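The tests in this part were chosen after the values had been seen, and only the prediction for large barcodes absent from another library was written before its value was known. Recurrence of barcodes differed between identifiers. For GTTG, 3680 distinct barcodes were counted as colonies and a single sample held up to 1642. For AACC the values were 7661 and 2074. GCTA, with 37 distinct barcodes, had 89.5% of its colonies in 2 or more samples, while ACAC, with 381, had 4.11%.

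Median colony size rose with recurrence, from 12.4 RPM for barcodes of 1 sample to 22.1 for those of 2, 57.0 for those of 4 and 279 for those of 9. Part of this rise lies between identifiers, as AACC and GTTG have both larger colonies and more recurring barcodes. Within identifiers, barcodes of several samples had a median log2 size 0.47 above that of barcodes of 1 sample. The size of a shared barcode in a sample told little of its size in another. Across shared barcodes, which are not independent replicates, the median Spearman correlation over pairs of samples was 0.104 for AACC (55 pairs), 0.143 for GTTG (51 pairs) and 0.125 for CCTT (55 pairs), with single pairs from -0.257 to 0.387.

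Barcodes shared between samples could come from clones that had divided before injection, from reads carried between libraries, or from separate cells with the same random bases. The ratio of the smaller to the larger read number over shared pairs, tried first, had a median of 0.232 and of 0.203 with sizes shuffled within identifiers, so it cannot tell carried reads from other sources. Reads carried at a rate high enough to pass the minimum would put most large barcodes of a library into another, but a median of 79.1% of the barcodes with 1000 or more reads had 0 reads in another library (61.1% in the lowest of 110 ordered pairs), which argues against carried reads as the main source. The base frequencies predicted 22.3 shared pairs by coincidence where 38291 were seen. This prediction takes the bases of every barcode as drawn independently at each position. It therefore does not cover separate cells tagged with a sequence that was repeated in the tagging pool. Barcodes of several samples were larger in median in 27 of 31 identifiers (exact two-sided sign test p = 3.4e-05). This cannot tell whether clones had divided before injection, since barcodes that grow larger also pass the minimum in more samples, and the weak correlations of size between samples leave that open.

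Identifier GATC stood apart in its sizes. Its 3301 distinct barcodes had at most 28 reads in a library. Over its 4437 listings with 2 or more reads, pooled over the libraries, the ratio of the 99th percentile to the median was 3.33. The same ratio was 13.8 or more in 30 other identifiers. It made up 0.0246% of all reads. Sequencing errors of another identifier were argued against, as 0.0206% of its barcodes shared their random bases with another identifier of the same library. A candidate explanation is the spike-in line, added after growth, and another is cells of the pool that lodged in the lung and did not grow. These cannot be told apart here: the number of GATC barcodes was not clearly related to the number of other colonies over 11 samples (Spearman rho = -0.491, permutation p = 0.131; Pearson r = -0.571, permutation p = 0.0642; adjusted p = 0.131 and 0.128 over the 2 permutation tests; r = -0.286 without the 2 samples farthest from the median). If GATC were the spike-in, the ratio of other reads to GATC reads would measure burden, and its log2 difference between the groups was 0.55 with an SE of 0.52 (exact permutation p = 0.342).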
